A study of Rattus norvegicus with 51 samples.

How the data were processed

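Total RNA of engineered tissues of neonatal rat ventricular myocytes was hybridized to 51 Affymetrix arrays, in 16 groups defined by time (0, 6, 24 or 96 h), coating (isotropic or anisotropic fibronectin) and stretch (none, isotropic tissue stretched, longitudinal or transverse). The 0 h group had 6 arrays, 1 from each of 6 primary harvests, and each of the other 15 groups had 3. Per the labels' protocols the cells were kept in supplemented M199 with 10% serum for 48 h and 2% serum after that, RNA was extracted with a Stratagene miniprep kit, and 1 µg of total RNA was labelled with biotin. The amplitude and rate of the stretch and the age of the animals were not given in the sources used here.

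The authors deposited log2 signal values of 29214 probe sets, made from the array files with RMA in Affymetrix Expression Console per the submitters' processing notes, in a pair of tables that hold identical values (largest difference 0). They also deposited log2 fold changes of the 15 later groups against the 0 h group and p-values beside them, for which limma is named in the processing notes. Versions and the way the authors adjusted the deposited p-values were not given in the sources used here. The deposited fold changes equalled plain differences of group means, without a harvest term, for 13 of 15 columns (median absolute difference under 0.001), and 1 of these columns is headed 96 h but holds the 24 h isotropic unstretched group. They served only to check the labels.

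Array medians of log2 signal ran from 5.31 to 5.43, maxima from 13.3 to 13.6, the lowest value was 2.67, and Pearson's r between arrays across probe sets was 0.9464 to 0.9982. Exactly 1 gene symbol was attached to 20360 probe sets, none to 8792 and several to 62, per the deposited annotation. For each symbol the probe set with the highest mean was kept (1022 genes had more than 1), which left 18602 genes, and no filter on signal was applied. Probe sets without a single symbol were left out of the gene tests, since their gene is not known, and were tested apart. The reference table of gene names served only to match synonyms of list members.

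The groups, tests, gene lists and rules for named genes were fixed before the data were examined. The main test was limma 3.58.1 in R 4.3.3 with the data.table package (version 1.17.8). A linear model with a mean per group and a term per harvest was fitted to all 51 arrays (30 residual degrees of freedom), with moderated variances and Benjamini-Hochberg adjustment per comparison at 0.05. There were 18 comparisons between groups: stretch against no stretch in isotropic tissue, longitudinal and transverse stretch against no stretch in anisotropic tissue, transverse against longitudinal stretch, and anisotropic against isotropic unstretched tissue, each at 3 times, and isotropic unstretched tissue of each time against 0 h. A further 6 F tests asked whether the stretch response differed with tissue layout at each time or changed over time. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

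Harvest, as the labels give it for each array, is what pairs the arrays. Replicate numbers are not used, since the same number stands for different harvests in different groups. The pairing was checked on deviations from group means: arrays of the same harvest in different groups had a mean r of 0.2193 (220 pairs, 92.73% above 0), arrays of different harvests -0.04836 (995 pairs, 39.5% above 0), and the mean within a harvest ran from 0.1109 to 0.2846.

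Named genes were those past the threshold with the same sign in every harvest that held both groups, up to 4 largest rises and 4 largest falls. To these were added up to 4 of the largest changes past the threshold in each list, and 11 genes fixed beforehand: Nppa, Nppb, Acta1, Myh6, Myh7, Atp2a2, Ankrd1, Ctgf, Gja1, Col1a1 and Fos. Loci without a gene name were skipped. A few genes that this rule would name are not reported here. For F tests the 6 genes with the smallest p were eligible.

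The 31 lists were tested with camera of limma at a preset correlation of 0.01 between genes, adjusted over 558 tests, and again with an estimated correlation. They were the foetal and hypertrophic programme, sarcomere, calcium handling, ion channels, intercalated disc, immediate early response, YAP and TEAD targets, SRF and MRTF targets, extracellular matrix, integrins and focal adhesion, fatty acid oxidation, glycolysis, oxidative phosphorylation, cell cycle, cytokines and inflammation, interferon response, unfolded protein response, heat shock, antioxidant response, apoptosis and p53 targets, receptors of the angiotensin, endothelin, adrenergic and natriuretic systems, growth factors, cholesterol synthesis, and markers of cardiomyocytes, fibroblasts, smooth muscle and pericytes, endothelium, macrophages, epicardium and mesothelium, Schwann cells and neurons, and erythroid cells.

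The procedure was tested on simulated data of 18602 genes with the same design, with 50 genes changed at each of 4 sizes. Comparisons between groups recovered 76 to 94% of genes changed 1.5-fold and 92 to 100% of those changed 2-fold, F tests of tissue layout 78% at 1.5-fold, and F tests over time 58 to 66% at 1.5-fold and 90 to 92% at 2-fold. Among unchanged genes 5 to 19 were called.

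Alternatives written beforehand were no harvest term, harvest as a random block, subtraction of each harvest's own 0 h array, a fit to the arrays of the time point and 0 h alone, dim genes left out, moderated variances with trend and robust options, quantile normalisation repeated, the second deposited value table, the mean of all probe sets of a gene for named genes, an estimated correlation for list tests, and each array left out in turn. Exchanging 2 arrays between groups, and leaving both out, were chosen after the data were seen.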

Results

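Neonatal rat ventricular myocytes of the Sprague-Dawley strain were grown on silicone membranes that carried fibronectin either as an even coat (isotropic tissue) or as a micropattern (anisotropic tissue). After 1 h of attachment, the 0 h point, tissues stayed unstretched or were stretched cyclically for 6, 24 or 96 h, and anisotropic tissue was stretched along its pattern (longitudinal) or across it (transverse). RNA of 6 primary harvests was measured on 51 Affymetrix arrays in 16 groups, with n = 6 at 0 h, 1 array per harvest, and n = 3 in each of the other 15 groups. The number of arrays limits the precision. The deposited log2 signals of 18602 genes were compared with limma, with harvest as a term, so that each p-value rests on the spread between arrays that remains within groups after harvest differences are removed. A log2 change is the first group named minus the second as estimated in this fit, adjusted for harvest, given with ± its standard error. It can differ from the plain difference of the group means. Where 1 array left out changed a result, it is named by its group, U for unstretched, S for stretched isotropic, L for longitudinally and T for transversely stretched, and its replicate number. Counts that moved by over 1.5 times with each harvest's own 0 h array subtracted (O), in a fit to the arrays of the time point and 0 h alone (P), with dim genes left out (D) or with harvest as a random block (R) carry that letter. Counts of list members adjusted over the list alone are given where they differ from the counts over all genes. The design asks which transcripts stretch changes, how soon, and whether the layout of the tissue and the direction of the stretch alter that response.

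A pair of isotropic arrays lay apart from the groups of their labels. On an axis from unstretched anisotropic tissue of 24 h (position 0) to that of 96 h (position 1), replicate 1 of the 24 h isotropic stretched group lay at 0.92, and the other two replicates lay at 0.0381 and 0.107. Replicate 1 of the 96 h isotropic unstretched group lay at 0.233, and the other two lay at 1 and 1.03. Of 15 fold change columns in the authors' deposited table, 13 equalled the differences of group means as labelled (median absolute difference under 0.001), and all 15 did so with these 2 arrays exchanged. With the arrays as labelled, the 2 unmatched columns of the authors' deposited table differed from those differences by a median of 0.0553. The labels as given were used for every main count, and counts with the 2 arrays exchanged, a choice made after the data were seen, stand beside them where they differ by more than 1.5 times. The median residual SD over genes was 0.1195 as labelled and 0.1134 exchanged.

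**Figure D1:**
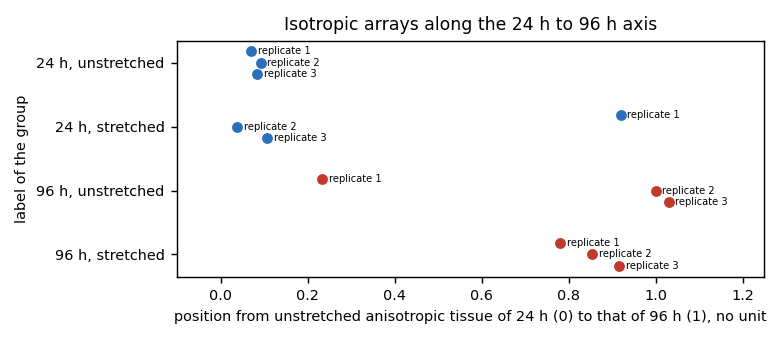
Position of each isotropic array of 24 and 96 h (1 point per array, no unit) along the axis from unstretched anisotropic tissue of 24 h (0) to that of 96 h (1), by the group on its label. Replicate 1 of the 24 h stretched group sits at 0.92 and replicate 1 of the 96 h unstretched group at 0.233.

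**Figure D2:**
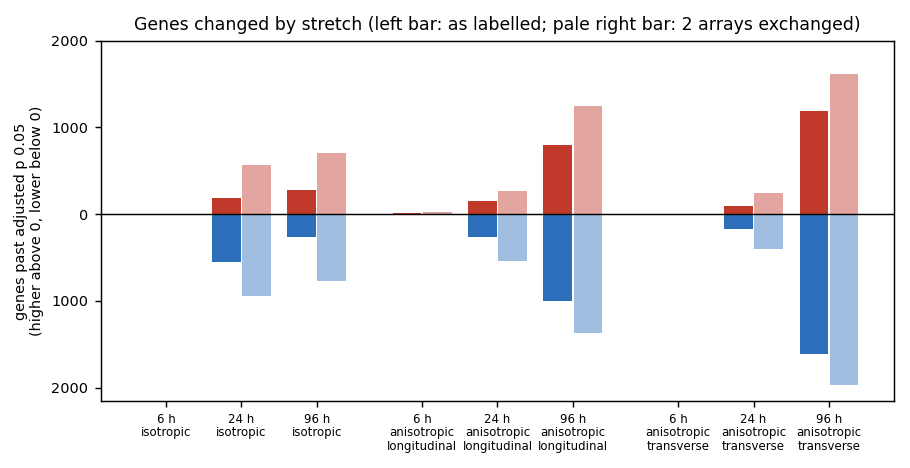
Genes past adjusted p 0.05 in each stretch comparison (3 arrays against 3), higher above 0 and lower below 0, as labelled (left bars) and with the 2 arrays exchanged (pale right bars). Transverse stretch of 96 h had the highest count, 2797, and transverse stretch of 6 h had 0.

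The first comparison asked what 6 h of stretch changed in isotropic tissue. Lmod2, a leiomodin that elongates thin filaments of the sarcomere, rose by 0.89 ± 0.16 (adjusted p = 0.045) and was the only gene to pass, with a positive difference in 3 of the 3 harvests that held both groups. At unadjusted p under 0.05 there were 359 genes. Changes that did not pass included Nppb (0.59), Ankrd1 (0.26), Ctgf (0.71) and Nppa (0.10), which encode B-type natriuretic peptide, a sarcomeric stress protein, connective tissue growth factor and atrial natriuretic peptide. No member of the foetal and hypertrophic list passed out of 12 (median 0.23, adjusted p = 0.00027, adjusted p = 0.39 with an estimated correlation, 1 higher and 0 lower adjusted over the list alone). In the sarcomere list 1 of 22 rose (median 0.03, adjusted p = 0.017, adjusted p = 0.65 with an estimated correlation). No interferon response gene passed out of 18 (median -0.18, adjusted p = 4.9e-05, adjusted p = 0.36 with an estimated correlation). Among markers of other cells, 0 of 9 endothelial genes passed (median -0.17, adjusted p = 0.00016, adjusted p = 0.24 with an estimated correlation). Of 5 erythroid genes 0 passed (median -0.56, adjusted p = 8.4e-07, adjusted p = 0.060 with an estimated correlation, 0 higher and 3 lower adjusted over the list alone). With the 2 arrays exchanged or both left out 0 genes passed. The erythroid list, whose call as labelled hung on the preset correlation, passed with either when they were exchanged (adjusted p = 0.016 with an estimated correlation). The Lmod2 call was lost without the harvest block (0 genes) and with most single arrays left out: the count was 0 (O), 13 (P), 0 without U1, 0 without U2, 0 without U3, 0 without S1, 3 without S2 and 0 without S3.

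After 24 h the isotropic response had grown to 731 genes, 182 higher and 549 lower, of which 356 differed by at least 1.5-fold. Largest among the rises were Casq1 (1.82 ± 0.31, adjusted p = 0.00035), a calcium buffer of the sarcoplasmic reticulum, Slc7a3 (1.79 ± 0.49), a transporter of cationic amino acids, Adamts8 (1.58 ± 0.35), a secreted metalloproteinase, and Xirp2 (1.53 ± 0.36), an actin-binding protein of the intercalated disc. Largest among the falls were Reg3b (-3.27 ± 0.60, adjusted p = 0.00082), a secreted lectin, Hbb (-2.59 ± 0.59), beta haemoglobin, Aldoc (-2.42 ± 0.40), a glycolytic aldolase, and Ccl12 (-2.39 ± 0.62), a chemokine. By the naming rule the sign held in all 3 harvests with both groups. Among the genes fixed beforehand, Nppa (0.80 ± 0.23) rose, and Myh6 (-0.40 ± 0.11), Atp2a2 (-0.54 ± 0.11) and Gja1 (-0.61 ± 0.13) fell; these encode the alpha myosin heavy chain, the calcium pump of the sarcoplasmic reticulum and connexin 43. Nppb (0.05), Acta1 (0.48) and Ctgf (0.87) did not pass.

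By gene list, 8 of 18 interferon response genes fell after 24 h, none rose and 10 did not pass (median -0.51, adjusted p = 1.2e-13, adjusted p = 0.032 with an estimated correlation, 0 higher and 12 lower adjusted over the list alone), among them Mx2 (-2.25 ± 0.30), Usp18 (-2.12 ± 0.23) and Irf7 (-0.84 ± 0.14). In the foetal and hypertrophic list 3 of 12 rose, Nppa, Gdf15 (1.47) and Fhl1 (0.93), and the metallothionein Mt1a (-0.89) fell (median 0.37, adjusted p = 0.0093, adjusted p = 0.59 with an estimated correlation). Of 17 calcium handling genes 4 fell, among them Ryr2 (-0.73) and Pln (-0.36), the release channel and phospholamban (median -0.25, adjusted p = 0.0064, adjusted p = 0.59 with an estimated correlation, 0 higher and 6 lower adjusted over the list alone). Integrin and focal adhesion genes rose in 5 and fell in 1 of 27 cases, with Itga6 (0.98) and Actn1 (0.64) higher (median 0.16, adjusted p = 0.00052, adjusted p = 0.53 with an estimated correlation, 9 higher and 2 lower adjusted over the list alone). In the SRF and MRTF list 3 of 17 rose, led by the calponin Cnn1 (1.34) (median 0.09, adjusted p = 0.036, adjusted p = 0.65 with an estimated correlation, 4 higher and 0 lower adjusted over the list alone). Of 19 receptors and related genes of the angiotensin, endothelin, adrenergic and natriuretic systems 4 fell and 15 did not pass, with Ace (-1.19) and Adra1b (-1.01) as examples (median -0.06, adjusted p = 0.11, 1 higher and 4 lower adjusted over the list alone). The cell cycle list had 2 of 33 lower (median -0.39, adjusted p = 3.2e-06, adjusted p = 0.72 with an estimated correlation, 0 higher and 6 lower adjusted over the list alone).

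Markers of other cells also moved at 24 h. Fibroblast markers fell in 4 of 10 cases, Dcn (-1.74), Lum (-1.71), Pdgfra (-1.49) and Tcf21 (-1.34) (median -0.24, adjusted p = 0.0016, adjusted p = 0.62 with an estimated correlation). Endothelial markers fell in 4 of 9, with Tie1 (-0.79) and Emcn (-0.72) (median -0.44, adjusted p = 1.5e-05, adjusted p = 0.15 with an estimated correlation, 0 higher and 6 lower adjusted over the list alone). Macrophage markers fell in 3 of 12, the complement genes C1qc (-1.31), C1qa (-0.91) and C1qb (-0.58) (median -0.14, adjusted p = 0.0092, adjusted p = 0.63 with an estimated correlation). Dcn and Lum also stand in the extracellular matrix list, where 2 of 33 rose and 3 fell (median -0.03, adjusted p = 0.48, 2 higher and 4 lower adjusted over the list alone). Of 5 erythroid genes Hbb alone fell (median -0.92, adjusted p = 0.047, adjusted p = 0.59 with an estimated correlation, 0 higher and 3 lower adjusted over the list alone). With the 2 arrays exchanged 1513 genes passed, and 1198 with both left out. Under both labellings 572 passed, all in the same direction. Without the harvest block the count was 335, and Actn1, C1qa, C1qb, Cnn1, Lum, Mt1a, Myh6, Nppa, Pln, Ryr2, Slc7a3 and Xirp2 no longer passed. The count was 198 (O), 222 (P), 263 without U1 and 1109 without S3. Quantile scaling repeated over the arrays gave 266 higher and 454 lower genes. Exchanged, Hbb lay at -1.45 and Ccl12 at -1.48, and Ctgf passed at 1.09. With both arrays left out Hbb lay at -1.61 and C1qa at -1.42, and Ccl12 (adjusted p = 0.090), Myh6 (adjusted p = 0.059) and Nppa (adjusted p = 0.18) no longer passed. Leaving out any 1 array in brackets ended the calls of Myh6 (U1, U2, U3, S1, S2), Lum and Pln (U1, U2, U3, S2) and Mt1a and Ryr2 (U1, U2, S1, S2). Slc7a3 and C1qa (U1, U2, S2, S3), Ccl12 (U1, U2, S1) and Gdf15 (U1, U2, S2) were lost too. Adamts8 (U1, S3), Nppa (U1, S1) and Xirp2, Actn1, C1qb and Fhl1 (U1, S2) also ended. Adra1b, Cnn1 and Itga6 (U1) and Hbb (S1) were lost too.

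At 96 h of isotropic stretch 546 genes passed, 280 higher and 266 lower, and 247 of them differed by at least 1.5-fold. Adamts8 (2.61 ± 0.35, adjusted p = 3.2e-05) rose 6.12-fold, from a mean log2 signal of 6.85 ± 0.80 (SD) to 9.47 ± 1.07. The other large rises were Fibin (1.90 ± 0.31), Lox (1.73 ± 0.41) and Fndc1 (1.71 ± 0.35), of which Lox encodes the enzyme that cross-links collagen and elastin. C7 (-2.67 ± 0.66, adjusted p = 0.019), a complement component, Ptn (-2.38 ± 0.45), the growth factor pleiotrophin, Col14a1 (-2.26 ± 0.37), a fibril-associated collagen, and Ccl7 (-2.06 ± 0.56), a chemokine, fell most. By rule the sign held in 3 of 3 harvests. Of the 11 genes fixed beforehand only Myh7 (0.34 ± 0.10), the beta myosin heavy chain, rose, and Acta1 (-0.88), Myh6 (-0.24), Nppa (0.17) and Ctgf (0.46) did not pass.

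Macrophage markers fell in 6 of 12 cases at 96 h, with Cd68 (-1.43 ± 0.32), Mrc1 (-1.26 ± 0.26) and Csf1r (-0.91 ± 0.22) as examples (median -0.81, adjusted p = 7.1e-12, adjusted p = 0.080 with an estimated correlation, 0 higher and 11 lower adjusted over the list alone). Fibroblast markers fell in 2 of 10, Dcn (-1.50) and Tcf21 (-1.51) (median -0.55, adjusted p = 0.012, adjusted p = 0.69 with an estimated correlation, 0 higher and 3 lower adjusted over the list alone). In the cell cycle list 1 of 33 passed, the thymidylate synthase gene Tyms (-0.39) (median -0.70, adjusted p = 3.2e-13, adjusted p = 0.57 with an estimated correlation, 0 higher and 17 lower adjusted over the list alone). Integrin and focal adhesion genes rose in 5 of 27 cases, among them Itga5 (0.69), Ptk2 (0.51) and Itgb5 (0.50) (median 0.14, adjusted p = 3.9e-06, adjusted p = 0.36 with an estimated correlation, 10 higher and 1 lower adjusted over the list alone). In the extracellular matrix list 4 of 33 rose, Lox and Timp3 (1.48) among them, and Dcn and Col6a1 (-1.18) fell (median 0.24, adjusted p = 0.0017, adjusted p = 0.77 with an estimated correlation, 5 higher and 2 lower adjusted over the list alone). Of 26 growth factors 4 rose, led by Inhba (1.29) and Fgf9 (1.15) (median 0.05, adjusted p = 0.046, adjusted p = 0.53 with an estimated correlation, 6 higher and 2 lower adjusted over the list alone). In the cytokine and inflammation list 3 of 22 fell, Ccl7, Il1rl1 (-1.75) and Icam1 (-0.84) (median -0.23, adjusted p = 0.00052, adjusted p = 0.61 with an estimated correlation, 1 higher and 6 lower adjusted over the list alone). No cholesterol synthesis gene passed out of 17 (median 0.47, adjusted p = 4.9e-08, adjusted p = 0.55 with an estimated correlation, 5 higher and 0 lower adjusted over the list alone).

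These 96 h isotropic values depended on the arrays used. With the 2 arrays exchanged 1483 genes passed, and 1112 did with both left out. Without the harvest block 230 passed, Ccl7, Col6a1, Csf1r, Dcn, Myh7 and Tyms not among them, and 455 passed under both labellings. Exchanged, 10 macrophage markers and 5 fibroblast markers fell. The macrophage list passed (adjusted p = 0.024 with an estimated correlation). The cholesterol synthesis list had a median of 0.12 (adjusted p = 0.099). The extracellular matrix list had a median of -0.11 (0.24 as labelled), and Ccl7 (-1.19) no longer passed. Lox then lay at 1.12, Fibin at 1.47, Fndc1 at 1.44 and Adamts8 at 3.155. C7 lay at -3.57, Ptn at -2.95 and Col14a1 at -2.60. With both arrays left out Lox (0.89, adjusted p = 0.054) and Ccl7 no longer passed, and Fndc1 lay at 1.12 and C7 at -4.07. The count was 91 (O), 858 without U1, 337 without U3, 194 without S1 and 297 without S3. Calls lost without any 1 of the arrays in brackets were those of Myh7 (U2, U3, S1, S2, S3), C7, Col6a1 and Tyms (U2, U3, S1, S3) and Ccl7 (U1, S1, S2, S3). Cd68 (U2, U3, S1), Lox (U1, S1, S3) and Csf1r (U2, S1) were lost in the same way. Dcn and Itgb5 (S1), Fndc1 (S3) and Itga5 and Mrc1 (U2) also ended so.

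**Figure D3:**
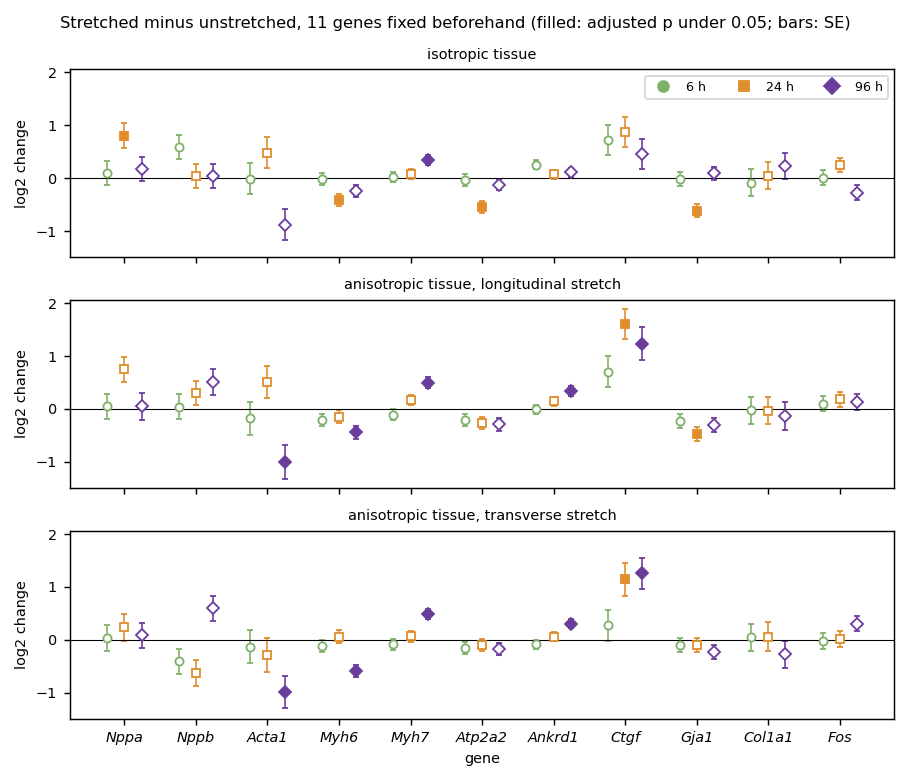
Log2 change, stretched minus unstretched (3 arrays against 3), of the 11 genes fixed beforehand at 6 h (circles), 24 h (squares) and 96 h (diamonds); bars are the SE of the fit and filled symbols passed. Ctgf reached 1.61 after longitudinal and 1.26 after transverse stretch.

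In anisotropic tissue the early question was what 6 h of longitudinal stretch changed. 18 genes rose and none fell. Csf2 (2.38 ± 0.20, adjusted p = 3.6e-09), which encodes granulocyte-macrophage colony-stimulating factor, rose 5.2-fold by fit (plain log2 means 4.77 ± 0.51 (SD) to 7.30 ± 0.45). Cxcl2 (2.21 ± 0.38), a neutrophil chemokine, Il1a (2.13 ± 0.35), interleukin 1 alpha, and Nos2 (1.90 ± 0.30, adjusted p = 0.00069), inducible nitric oxide synthase, followed. By rule each rose in the 1 harvest with both groups. In the cytokine and inflammation list 3 of 22 rose (median 0.33, adjusted p = 1.8e-11, adjusted p = 0.24 with an estimated correlation, 5 higher and 0 lower adjusted over the list alone). None of 17 unfolded protein response genes passed (median 0.23, adjusted p = 0.00010, adjusted p = 0.44 with an estimated correlation). The same held for 16 intercalated disc genes (median -0.19, adjusted p = 0.00018, adjusted p = 0.30 with an estimated correlation). It also held for 17 calcium handling genes (median -0.17, adjusted p = 0.00019, adjusted p = 0.39 with an estimated correlation). Macrophage markers had 0 of 12 past the test (median 0.07, adjusted p = 0.27, 2 higher and 0 lower adjusted over the list alone). None of the 11 genes fixed beforehand passed, with Ctgf at 0.70 and Gja1 at -0.22. As labelled the cytokine list passed with the preset correlation alone, and with the 2 arrays exchanged it passed with both (adjusted p = 0.036 with an estimated correlation). The count was 11 (O), 63 (P) and 3 (D). Any 1 of the arrays in brackets, when left out, ended the calls of Cxcl2 (U1, L3).

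By 24 h longitudinal stretch had changed 414 genes, 147 higher and 267 lower. Fstl3 (2.24 ± 0.34, adjusted p = 0.00027), a binder of activins, Cnn1 (2.20 ± 0.36), Adamts8 (2.15 ± 0.36) and Il11 (2.06 ± 0.34), a cytokine of the interleukin 6 family, rose most. Mx2 (-1.83 ± 0.31, adjusted p = 0.00075), an interferon-induced GTPase, Lum (-1.71 ± 0.45), the proteoglycan lumican, Lppr5 (-1.64 ± 0.34) and Tmem176a (-1.64 ± 0.31) fell most. By rule the sign held in the 2 harvests with both groups. Ctgf (1.61 ± 0.29) rose and Gja1 (-0.47 ± 0.13) fell, and Nppa (0.75), Nppb (0.30) and Acta1 (0.51) did not pass. In the foetal and hypertrophic list Gdf15 (1.47) and Fhl1 (1.04) rose and 10 of 12 did not pass (median 0.60, adjusted p = 1.7e-05, adjusted p = 0.30 with an estimated correlation, 5 higher and 1 lower adjusted over the list alone). Of 17 SRF and MRTF targets 5 rose, Tagln (0.95) and Itga5 (0.92) among them (median 0.08, adjusted p = 9.7e-05, adjusted p = 0.36 with an estimated correlation). Integrin and focal adhesion genes rose in 6 and fell in 1 of 27 cases (median 0.17, adjusted p = 5.3e-06, adjusted p = 0.36 with an estimated correlation, 12 higher and 1 lower adjusted over the list alone).

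Cell cycle genes fell in 4 of 33 cases after 24 h of longitudinal stretch, all 4 of them subunits of the replicative helicase, Mcm5 (-0.74), Mcm6 (-0.73), Mcm3 (-0.64) and Mcm2 (-0.49) (median -0.62, adjusted p = 3.4e-13, adjusted p = 0.57 with an estimated correlation, 0 higher and 11 lower adjusted over the list alone). Of 18 interferon response genes 5 fell, with Usp18 (-1.44) beside Mx2 (median -0.31, adjusted p = 5.3e-09, adjusted p = 0.13 with an estimated correlation, 0 higher and 9 lower adjusted over the list alone). In the intercalated disc list Xirp2 (1.98) and Nrap (0.87) rose and Gja1 fell (median -0.12 but mean 0.03 and test direction down, adjusted p = 0.82, 2 higher and 4 lower adjusted over the list alone). Fibroblast markers fell in 3 of 10 cases, Lum, Pdgfra (-1.57) and Tcf21 (-1.42) (median -0.35, adjusted p = 0.00017, adjusted p = 0.57 with an estimated correlation, 0 higher and 4 lower adjusted over the list alone). Macrophage markers fell in 2 of 12 (median -0.19, adjusted p = 0.066, 0 higher and 3 lower adjusted over the list alone). With the 2 arrays exchanged 803 genes passed, and 858 did with both left out. The count was 238 without the harvest block, which ended the calls of Gja1, Lum, Mcm2, Mcm3, Mcm5, Mcm6 and Tagln. It was also 122 (O), 27 (P), 223 without U1, 149 without U2, 256 without U3, 174 without L1 and 178 without L3. Leaving out any 1 array in brackets ended the calls of Lum, Mcm5 and Mcm6 (U1, U2, U3, L1, L2, L3), Gja1, Gdf15, Mcm3 and Tagln (U1, U2, U3, L1, L3) and Mcm2 (U1, U2, U3, L2, L3). Fhl1 (U2, L1, L3) and Tmem176a (L1) were lost in the same way.

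After 96 h of longitudinal stretch 1804 genes passed, 801 higher and 1003 lower, 846 of them by at least 1.5-fold. Adamts8 (3.54 ± 0.38, adjusted p = 3.1e-07) rose 11.6-fold by fit (plain log2 means 6.07 ± 0.15 (SD) to 9.56 ± 0.13). Pkp1 (2.27 ± 0.35), a desmosomal plakophilin, and Leprel1 (2.23 ± 0.30), a collagen prolyl hydroxylase, were among the next. C7 (-4.63 ± 0.72, adjusted p = 5.2e-05), Ptn (-3.47 ± 0.49), Col14a1 (-3.22 ± 0.40) and Figf (-3.12 ± 0.42), vascular endothelial growth factor D, fell most. By rule the sign held in the 1 harvest with both groups. Of the genes fixed beforehand Ctgf (1.23 ± 0.31), Myh7 (0.50 ± 0.10) and Ankrd1 (0.34 ± 0.09) rose, Acta1 (-1.01 ± 0.32) and Myh6 (-0.44 ± 0.12) fell, and Nppa (0.05), Nppb (0.50), Atp2a2 (-0.29) and Gja1 (-0.30) did not pass.

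Cell cycle genes fell in 16 of 33 cases at 96 h of longitudinal stretch, including Ccnb2 (-1.58), Ccnb1 (-1.56) and Kif20a (-1.44) (median -0.99, adjusted p = 1.1e-14, adjusted p = 0.53 with an estimated correlation, 0 higher and 28 lower adjusted over the list alone). Integrin and focal adhesion genes rose in 11 and fell in 1 of 27 cases, with Itga6 (1.23), Itga5 (0.98) and Itgb5 (0.81) as examples (median 0.34, adjusted p = 1.8e-07, adjusted p = 0.28 with an estimated correlation, 17 higher and 2 lower adjusted over the list alone). In the foetal and hypertrophic list 5 of 12 rose, Gdf15 (2.00) and Rcan1 (1.10) among them, and Acta1 and Mt1a (-1.10) fell (median 0.43, adjusted p = 0.012, adjusted p = 0.59 with an estimated correlation, 6 higher and 2 lower adjusted over the list alone). YAP and TEAD targets rose in 7 and fell in 2 of 22 cases, Tgfb2 (1.41) beside Ctgf against Igfbp3 (-1.05) and F3 (-0.96) (median 0.18, adjusted p = 0.15, 9 higher and 3 lower adjusted over the list alone). Of 26 growth factors 6 rose (median 0.11, adjusted p = 0.024, adjusted p = 0.44 with an estimated correlation, 9 higher and 1 lower adjusted over the list alone). In the oxidative phosphorylation list 5 of 35 fell, Cox8b (-1.06) and Ndufs3 (-0.50) among them (median -0.15, adjusted p = 5.2e-06, adjusted p = 0.65 with an estimated correlation). Ion channels rose in 1 case and fell in 4 of 21, with Kcnip2 (-0.91) and Kcnh2 (-0.65) (median -0.06, adjusted p = 0.23, 2 higher and 5 lower adjusted over the list alone). Sarcomere genes rose in 1 and fell in 3 of 22 cases (median 0.09 but mean -0.06 and test direction up, adjusted p = 0.65, 3 higher and 3 lower adjusted over the list alone).

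With the same 96 h stretch macrophage markers fell in 11 of 12 cases, with Cd68 (-2.61 ± 0.35), Mrc1 (-2.34 ± 0.29) and Lyz2 (-2.34 ± 0.59) as examples (median -1.08, adjusted p = 6.4e-15, adjusted p = 0.032 with an estimated correlation). Fibroblast markers fell in 5 of 10, Lum (-2.89), Dcn (-2.66), Thy1 (-2.30) and Tcf21 (-2.11) among them (median -1.36, adjusted p = 2.0e-07, adjusted p = 0.36 with an estimated correlation). Epicardial and mesothelial markers fell in 2 of 8, with Aldh1a2 (-1.33) (median -0.26, adjusted p = 0.018, adjusted p = 0.51 with an estimated correlation, 0 higher and 4 lower adjusted over the list alone). In the smooth muscle and pericyte list Mcam (1.24) and Cspg4 (0.86) rose and Rgs5 (-0.85) fell (median 0.17, adjusted p = 0.33). In the extracellular matrix list 2 rose and 5 fell of 33, Lum and Dcn again, Col6a1 (-1.69) and Eln (-1.68) (median -0.13, adjusted p = 0.099, 3 higher and 6 lower adjusted over the list alone). Acta1 no longer passed without the harvest block. With both isotropic arrays in doubt left out 2757 genes passed. The count was 822 (P), 1089 without U3, 1016 without L2 and 1123 without L3. Calls lost without any 1 of the arrays in brackets were those of Ccnb2 and Kcnh2 (U1, U3, L1, L2, L3), Acta1 (U1, U3, L1, L3) and Aldh1a2 (U2, U3, L1, L2). Ccnb1 and Kif20a (U1, U3, L2, L3), Thy1 (U2, U3, L2, L3) and Kcnip2 (U1, L1, L3) were lost in the same way. Myh6 (U1, U3, L2), Rcan1 and Tgfb2 (U3, L2) and Rgs5 (U3, L3) also ended so. Ankrd1 (L2), Ctgf (U3) and Lyz2 and Mt1a (L3) were lost in the same way.

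Transverse stretch of 6 h changed no gene at adjusted p under 0.05 in limma, and 575 genes had an unadjusted p under 0.05. The 18 genes that 6 h of longitudinal stretch raised did not pass here, and the fixed genes included Ctgf (0.27), Nppb (-0.41) and Nppa (0.04). Oxidative phosphorylation genes had 0 of 35 past the test (median -0.06, adjusted p = 0.00017, adjusted p = 0.74 with an estimated correlation). Endothelial markers had 0 of 9 (median -0.16, adjusted p = 0.0029, adjusted p = 0.38 with an estimated correlation). The count was 1 without T3.

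At 24 h transverse stretch had changed 271 genes, 100 higher and 171 lower. Fstl3 (1.95 ± 0.35, adjusted p = 0.0030), Syt11 (1.55 ± 0.24), a synaptotagmin of vesicle traffic, Adamts8 (1.53 ± 0.38) and Pkp1 (1.34 ± 0.35) rose most. Mx2 (-1.65 ± 0.32, adjusted p = 0.0073), Ifitm1 (-1.51 ± 0.30), Usp18 (-1.45 ± 0.24) and Hist1h1a (-1.41 ± 0.26), a linker histone, fell most. By rule the sign held in the 1 harvest with both groups. Ctgf (1.14 ± 0.31) rose, and Nppa (0.24), Nppb (-0.63) and Gja1 (-0.10) did not pass. Of 33 cell cycle genes 3 fell, Mcm6 (-0.86), Mcm5 (-0.83) and Pcna (-0.76) (median -0.52, adjusted p = 3.4e-11, adjusted p = 0.59 with an estimated correlation, 0 higher and 10 lower adjusted over the list alone). Interferon response genes fell in 3 of 18 cases, Mx2, Usp18 and Ifi27 (-0.93) (median -0.28, adjusted p = 5.6e-09, adjusted p = 0.13 with an estimated correlation, 0 higher and 7 lower adjusted over the list alone). No oxidative phosphorylation gene passed out of 35 (median -0.14, adjusted p = 2.9e-09, adjusted p = 0.59 with an estimated correlation, 0 higher and 7 lower adjusted over the list alone). Of 10 fibroblast markers Tcf21 (-1.40) and Pdgfra (-1.28) fell (median -0.26, adjusted p = 0.0018, adjusted p = 0.63 with an estimated correlation, 0 higher and 4 lower adjusted over the list alone). Of 9 endothelial markers Emcn (-0.67) fell (median -0.28, adjusted p = 0.00061, adjusted p = 0.30 with an estimated correlation, 0 higher and 3 lower adjusted over the list alone).

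The transverse count of 24 h moved with nearly any change of arrays. It was 647 with the 2 arrays exchanged and 692 with both left out. It was also 131 (O), 6 (P), 117 without U1, 51 without U2, 170 without U3, 694 without T1, 37 without T2 and 577 without T3. Calls lost without the harvest block were Emcn, Ifi27, Mx2 and Pkp1. Any 1 of the arrays in brackets, when left out, ended the calls of Adamts8, Pkp1 and Pdgfra (U1, U2, U3, T1, T2), Ctgf, Mcm5 and Mcm6 (U1, U2, U3, T2, T3) and Emcn (U1, U2, T1, T2). Pcna (U1, U2, T2) and Ifi27 (U2, T2) were lost in the same way. Fstl3, Ifitm1 and Hist1h1a (T2) and Mx2 (U2) also ended so.

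Transverse stretch of 96 h had the most changed genes of all the stretch comparisons, 2797, with 1188 higher and 1609 lower, 1110 of them by at least 1.5-fold. Adamts8 (3.81 ± 0.36, adjusted p = 8.6e-09) rose 14-fold by fit (plain log2 means 6.07 ± 0.15 (SD) to 9.91 ± 0.63). Leprel1 (2.61 ± 0.28) and Flt4 (1.96 ± 0.20), a receptor of vascular endothelial growth factors C and D, followed. C7 (-4.60 ± 0.68, adjusted p = 1.4e-05), Col14a1 (-3.59 ± 0.38), Ptn (-3.54 ± 0.46) and Dpt (-3.48 ± 0.33), dermatopontin of the extracellular matrix, fell most. By rule the sign held in the 2 harvests with both groups. Among the fixed genes Ctgf (1.26 ± 0.29), Myh7 (0.49 ± 0.10) and Ankrd1 (0.30 ± 0.08) rose, Acta1 (-0.99 ± 0.31) and Myh6 (-0.59 ± 0.12) fell, and Nppa (0.08), Nppb (0.60), Atp2a2 (-0.18) and Gja1 (-0.23) did not pass.

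All 33 of 33 cell cycle genes fell at 96 h of transverse stretch, with Ccnb1 (-2.36 ± 0.42), Top2a (-2.12 ± 0.44) and Rrm2 (-1.90 ± 0.42) as examples, a cyclin of mitosis, a topoisomerase and a subunit of ribonucleotide reductase (median -1.51, adjusted p = 1.6e-27, adjusted p = 0.30 with an estimated correlation). Integrin and focal adhesion genes rose in 14 and fell in 2 of 27 cases, Itga6 (1.49) and Itga5 (1.02) against the caveolin Cav1 (-1.35) (median 0.30, adjusted p = 2.6e-06, adjusted p = 0.36 with an estimated correlation, 16 higher and 2 lower adjusted over the list alone). In the foetal and hypertrophic list 6 of 12 rose, Gdf15 (1.85), Rcan1 (1.39) and Xirp1 (1.04) among them, and Acta1 and Mt1a (-0.89) fell (median 0.47, adjusted p = 0.016, adjusted p = 0.61 with an estimated correlation, 7 higher and 2 lower adjusted over the list alone). SRF and MRTF targets rose in 6 and fell in 3 of 17 cases (median 0.18, adjusted p = 0.020, adjusted p = 0.63 with an estimated correlation, 8 higher and 3 lower adjusted over the list alone). YAP and TEAD targets rose in 8 and fell in 4 of 22 (median 0.20, adjusted p = 0.36, 10 higher and 6 lower adjusted over the list alone). Of 22 sarcomere genes 4 rose, Lmod2 (0.70) among them, and 4 fell, Myom2 (-2.29) and Nebl (-1.21) among them (median 0.10 but mean -0.14 and test direction up, adjusted p = 0.86, 6 higher and 5 lower adjusted over the list alone). Intercalated disc genes rose in 6 of 16 cases, including Xirp2 (1.14) and Pkp2 (0.67) (median 0.16, adjusted p = 0.058, 6 higher and 2 lower adjusted over the list alone). Heat shock genes rose in 4 of 15 (median 0.23, adjusted p = 0.042, adjusted p = 0.76 with an estimated correlation, 5 higher and 0 lower adjusted over the list alone). Cholesterol synthesis genes rose in 3 of 17, with Sc5dl (0.78) and Sc4mol (0.76) (median 0.42, adjusted p = 0.0016, adjusted p = 0.74 with an estimated correlation, 5 higher and 0 lower adjusted over the list alone). Of 17 apoptosis and p53 targets 4 rose, Cdkn1a (0.85) among them, and 2 fell (median 0.19, adjusted p = 0.29, 7 higher and 3 lower adjusted over the list alone).

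Macrophage markers fell in 11 of 12 cases beside these lists, with Lyz2 (-3.36 ± 0.55), Cd68 (-2.73 ± 0.33) and Mrc1 (-2.51 ± 0.27) (median -1.28, adjusted p = 1.5e-15, adjusted p = 0.032 with an estimated correlation). Of 10 fibroblast markers 5 fell, Lum (-3.25), Dcn (-3.03), Tcf21 (-2.55) and Pdgfra (-1.93) among them (median -1.45, adjusted p = 1.8e-08, adjusted p = 0.30 with an estimated correlation, 0 higher and 8 lower adjusted over the list alone). In the smooth muscle and pericyte list 3 rose, led by Mcam (1.57), and 3 of 9 fell, led by Pdgfrb (-1.13) (median 0.21, adjusted p = 0.59, 4 higher and 3 lower adjusted over the list alone). Of 7 Schwann cell and neuronal markers Tubb3 (-0.54) fell (median -0.02, adjusted p = 0.86). Extracellular matrix genes rose in 2 and fell in 6 of 33 cases, Eln (-2.31) and Col6a1 (-2.17) among the lower ones (median -0.29, adjusted p = 0.0033, adjusted p = 0.78 with an estimated correlation, 3 higher and 8 lower adjusted over the list alone). Cardiomyocyte markers rose in 2 and fell in 2 of 10 (median 0.11, adjusted p = 0.58, 5 higher and 2 lower adjusted over the list alone). Dropping the harvest block ended the calls of Mt1a and Xirp2. The count was 1473 (O) and 1601 without T1. Leaving out any 1 array in brackets ended the calls of Sc4mol and Sc5dl (U1, U2, U3, T1, T3), Xirp2 (U2, U3, T1, T2) and Mt1a (U1, U3, T1). Acta1 (U1, T1), Pdgfrb (U2, T1) and Cav1 and Xirp1 (T1) were lost in the same way. Myom2 (T3) and Tubb3 (U2) also ended so.

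**Figure D4:**
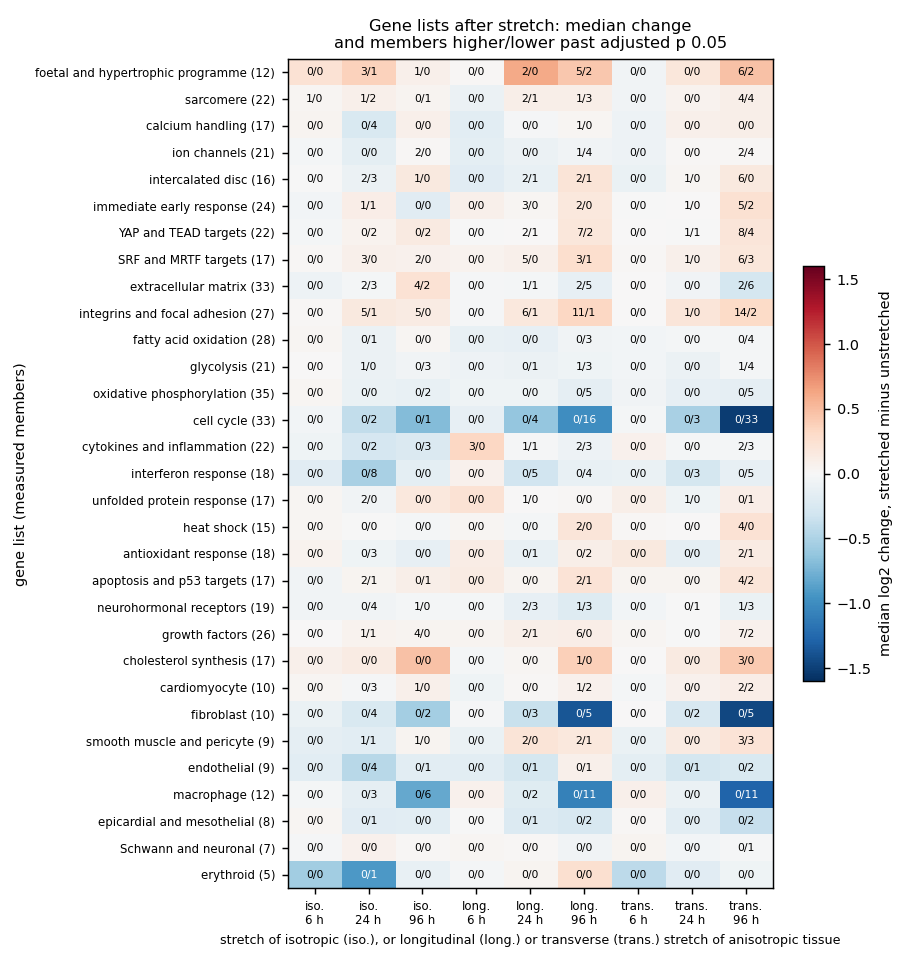
Median log2 change, stretched minus unstretched, of each gene list (rows, with measured members) in the 9 stretch comparisons (columns), and the number of members higher/lower past adjusted p 0.05. Cell cycle, macrophage and fibroblast lists had the lowest medians after 96 h of stretch of anisotropic tissue, -1.51, -1.28 and -1.45 in the transverse direction.

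Whether the direction of stretch mattered was tested by transverse minus longitudinal stretch. At 6 h 4 genes passed, all lower after transverse stretch: Csf2 (-1.72 ± 0.20, adjusted p = 5.5e-06), Csf3 (-1.001 ± 0.17), granulocyte colony-stimulating factor, Tfpi2 (-0.92 ± 0.18), an inhibitor of serine proteases, and Mmp3 (-0.85 ± 0.14), stromelysin 1. The sign was the same in 3 of the 3 harvests, which both directions shared. The cytokine list lacks Csf2 and Csf3, and 0 of 22 passed (0 higher and 4 lower adjusted over the list alone). Its median was -0.26 (adjusted p = 1.7e-14, adjusted p = 0.15 with an estimated correlation). It passed with the preset correlation alone as labelled and with both when exchanged (adjusted p = 0.016 with an estimated correlation). Tfpi2 then no longer passed (adjusted p = 0.066). No interferon response gene passed out of 18 (median -0.22, adjusted p = 7.0e-08, adjusted p = 0.19 with an estimated correlation). Without the harvest block 2 passed, and Csf3 and Tfpi2 did not. The count was 0 (D), 1 without L1, 2 without L3, 2 without T1, 8 without T2 and 2 without T3. Calls lost without any 1 of the arrays in brackets were those of Tfpi2 (L1, L2, L3, T1, T2, T3), Csf3 (L1, L3, T3) and Mmp3 (L1, T1).

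At 24 and 96 h limma called 0 genes between the directions, with 1458 and 1061 at unadjusted p under 0.05. Nppa differed by -0.51 ± 0.24 at 24 h and Ctgf by 0.02 ± 0.31 at 96 h. The foetal and hypertrophic list lay lower after transverse stretch at 24 h, with 0 of 12 past the test (median -0.36, adjusted p = 5.6e-05, adjusted p = 0.36 with an estimated correlation, 0 higher and 1 lower adjusted over the list alone). The cell cycle list lay lower after transverse stretch at 96 h, with 0 of 33 past the test (median -0.52, adjusted p = 8.8e-15, adjusted p = 0.53 with an estimated correlation, 0 higher and 3 lower adjusted over the list alone). At 24 h 4 genes passed when the 2 arrays were exchanged. The 24 h count was 8 without L2, 286 without T1 and 32 without T3, and the 96 h count was 15 without T2.

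Both directions of stretch were set against the same unstretched arrays, which by itself makes their changes alike. Across 18602 genes, which are not independent replicates, longitudinal and transverse changes had Pearson's r = 0.714 at 6 h, 0.771 at 24 h and 0.921 at 96 h. Simulated arrays without any effect of stretch gave a mean r of 0.526 ± 0.205 (SD), 0.513 ± 0.188 and 0.454 ± 0.213 over 200 draws. The covariance of the changes was 0.0106, 0.0331 and 0.0951, against 0.00931 ± 0.00701, 0.00904 ± 0.00587 and 0.00829 ± 0.00773 in the simulated arrays. At 96 h 617 genes rose and 871 fell in both directions, Adamts8 and C7 among them, and at 24 h 42 and 84. Over 100 draws of the simulated arrays no gene was shared at these times. Independent lists of these lengths would share 51.2 and 86.8 at 96 h and 0.79 and 2.45 at 24 h. The simulated count leaves out real effects and that of independent lists leaves out the shared unstretched arrays, whose part in the excess is unknown, and the excess does not measure a shared response.

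The micropattern alone was tested in unstretched tissue, anisotropic minus isotropic. At 6 and 24 h limma called 0 genes, with 246 and 582 at unadjusted p under 0.05. The foetal and hypertrophic list lay lower in anisotropic tissue at 24 h, with 0 of 12 past the test (median -0.41, adjusted p = 3.1e-06, adjusted p = 0.25 with an estimated correlation). The integrin and focal adhesion list lay lower too, with 0 of 27 (median -0.12, adjusted p = 3.9e-08, adjusted p = 0.24 with an estimated correlation, 0 higher and 1 lower adjusted over the list alone). At 96 h 3 genes passed: Coro2b (0.82 ± 0.16, adjusted p = 0.042) and Nckap1l (0.78 ± 0.14, adjusted p = 0.036), both regulators of actin, were higher and Tuba4a (-0.53 ± 0.09, adjusted p = 0.036), an alpha tubulin, was lower, in 3 of 3 harvests. No macrophage marker passed at 96 h out of 12 (median 0.49, adjusted p = 2.6e-08, adjusted p = 0.21 with an estimated correlation, 7 higher and 0 lower adjusted over the list alone). The foetal and hypertrophic list had 0 of 12 (median -0.57, adjusted p = 0.00019, adjusted p = 0.38 with an estimated correlation, 1 higher and 7 lower adjusted over the list alone). Extracellular matrix genes had 0 of 33 (median 0.50, adjusted p = 1.5e-09, adjusted p = 0.56 with an estimated correlation). Fibroblast markers had 0 of 10 (median 0.64, adjusted p = 1.9e-06, adjusted p = 0.39 with an estimated correlation, 2 higher and 0 lower adjusted over the list alone). With the 2 arrays exchanged 3 genes passed at 96 h, of which only Tuba4a was among these, and 0 passed with both left out. The extracellular matrix list then had a median of 0.09. Without the harvest block only Nckap1l passed at 96 h. The count was 0 (O), 0 (P), 1 (D), 12 (R), 0 without isotropic U1, 242 without isotropic U2, 7 without anisotropic U1, 22 without anisotropic U2 and 0 without anisotropic U3. The 24 h count was 39 without isotropic U1. Any 1 of the arrays in brackets, when left out, ended the calls of Coro2b (isotropic U1, anisotropic U1, anisotropic U3), Tuba4a (isotropic U1, isotropic U3, anisotropic U3) and Nckap1l (isotropic U1, anisotropic U3).

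Whether the stretch response depended on tissue layout was tested with an F statistic on the pair of differences between anisotropic and isotropic responses. At 6 h 5 genes passed, Csf2 (adjusted p = 3.1e-07), Tfpi2 (adjusted p = 0.0012), Csf3 (adjusted p = 0.0031), Mmp3 (adjusted p = 0.0040) and Slamf7 (adjusted p = 0.0064). The Csf2 response was larger than in isotropic tissue by 2.44 after longitudinal and by 0.72 after transverse stretch, and that of Mmp3 by 0.81 and -0.04. At 24 and 96 h limma called 0 genes, with 1117 and 1405 at unadjusted p under 0.05. The different counts of the 3 kinds of stretch at these times therefore do not by themselves show different responses. When the 2 arrays were exchanged 1 gene passed at 96 h, and with both left out 9 passed at 6 h. The 6 h count was 2 (O), 1 (D), 10 (R), 10 without anisotropic U3, 11 without S1, 3 without L2, 3 without L3 and 12 without T2. The 24 h count was 1 without isotropic U3, 55 without S3, 3 without L2, 102 without T1 and 11 without T3. The 96 h count was 1 without isotropic U1 and 22 without T2.

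Change of the stretch response over time was tested by an F statistic on the responses of 24 and 96 h, each minus that of 6 h. In isotropic tissue 64 genes passed, led by Neu1 (adjusted p = 2.4e-05), Vamp5 (adjusted p = 8.2e-05) and Lpar4 (adjusted p = 0.00060), a sialidase, a vesicle protein and a lysophosphatidic acid receptor. Longitudinal stretch had 325, with F3 (adjusted p = 1.5e-05), Csf2 (adjusted p = 1.6e-05) and Cd53 (adjusted p = 0.00021). The response of tissue factor F3 shifted by -1.19 at 24 h and -1.43 at 96 h, that of Csf2 by -2.21 at 24 h and -2.19 at 96 h, and that of the leukocyte tetraspanin Cd53 by -0.17 at 24 h and -2.29 at 96 h. Transverse stretch had 526, led by F3 (adjusted p = 1.1e-06), Kremen1 (adjusted p = 2.7e-06) and Tcf21 (adjusted p = 6.6e-05). The F3 response shifted by -1.11 at 24 h and -1.63 at 96 h. Myh7 passed in both directions of stretch, with 0.049 and 0.037 as adjusted p, and Nppa passed in none of the 3. Exchanging the 2 arrays gave 302, 822 and 1185 genes. Without the harvest block the isotropic count was 17 and the transverse count 339. The isotropic count was 9 (O), 42 without 6 h U2, 39 without 6 h U3, 42 without 6 h S2, 40 without 24 h U1, 42 without 24 h U2, 117 without 24 h S1, 41 without 24 h S2, 292 without 24 h S3, 187 without 96 h U1 and 29 without 96 h S1. The longitudinal count was 104 (O), 192 without 6 h U1, 171 without 6 h U2, 197 without 6 h L2, 154 without 6 h L3, 207 without 96 h U3, 542 without 96 h L1, 177 without 96 h L2 and 178 without 96 h L3. The transverse count was 141 (O), 339 without 6 h U1, 295 without 6 h U2, 264 without 6 h T2, 340 without 6 h T3, 323 without 96 h U1, 285 without 96 h U3 and 215 without 96 h T1.

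Time in culture without stretch was the largest contrast, isotropic tissue against the 0 h arrays of the 6 harvests. At 6 h 5893 genes passed (3561 higher, 2332 lower), at 24 h 6851 (3865 and 2986) and at 96 h 7050 (4059 and 2991). At 6 h Slc7a11 (3.36 ± 0.28, adjusted p = 1.8e-11), the cystine transporter, Slc7a3 (2.91 ± 0.44), Akr1b8 (2.88 ± 0.19), an aldo-keto reductase, and Hamp (2.84 ± 0.62), hepcidin, rose most. Fosb (-3.09 ± 0.11), Apold1 (-3.07 ± 0.13), Nr4a1 (-2.81 ± 0.23) and Npr3 (-2.76 ± 0.29), a natriuretic peptide receptor, fell most. At 24 h the extremes were Reg3b (5.67 ± 0.54, adjusted p = 1.2e-10), Ccl12 (4.36 ± 0.56) and Hamp (4.34 ± 0.62) and the complement protease C1s (3.63 ± 0.27) against Apold1 (-4.13 ± 0.13) and Gpr116 (-3.94 ± 0.15), the heat shock gene Hspa1b (-3.88 ± 0.14) and the fatty acid carrier Fabp4 (-3.85 ± 0.25). At 96 h they were Mmp12 (3.85 ± 0.47, adjusted p = 2.5e-08), Slc7a3 (3.58 ± 0.44), Gsta3 (3.47 ± 0.28) and Tagln (3.42 ± 0.23) against H19 (-4.69 ± 0.19), Hbb (-4.63 ± 0.53), Hba-a2 (-4.60 ± 0.73) and Gpr116 (-4.58 ± 0.15). By rule the sign held in 3 of 3 harvests. Of the fixed genes Nppa (1.13 ± 0.21), Nppb (1.56 ± 0.21), Ctgf (1.37 ± 0.25) and Ankrd1 (0.62 ± 0.07) had risen and Myh6 (-0.68 ± 0.10), Atp2a2 (-0.39 ± 0.10) and Gja1 (-0.63 ± 0.11) fallen by 96 h, while Myh7 lay at -0.14 and passed with the 2 arrays exchanged (-0.22).

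Endothelial markers fell in all 9 of 9 cases at each time, at 96 h with Tie1 (-3.95), Emcn (-3.70) and Cdh5 (-3.66) (median -2.72, adjusted p = 4.8e-20, adjusted p = 0.00033 with an estimated correlation). The median was -1.29 at 6 h and -2.75 at 24 h, with adjusted p = 0.0044 and adjusted p = 0.00038 with an estimated correlation. Immediate early genes fell in 20, 21 and 22 of 24 cases at 6, 24 and 96 h, with Fosb (-3.62), Nr4a1 (-3.59) and Fos (-2.72) at 96 h (median -1.24, adjusted p = 2.2e-18, adjusted p = 0.032 with an estimated correlation, 0 higher and 23 lower adjusted over the list alone). With the 2 arrays exchanged that list passed with the preset correlation alone (adjusted p = 0.071 with an estimated correlation). Fatty acid oxidation genes fell in 12, 21 and 23 of 28, Pdk4 (-2.63) and Hadh (-1.73) among them (median -0.69, adjusted p = 3.1e-12, adjusted p = 0.24 with an estimated correlation). Oxidative phosphorylation genes fell in 27 of 35 cases at 96 h (median -0.29, adjusted p = 1.5e-08, adjusted p = 0.59 with an estimated correlation, 0 higher and 28 lower adjusted over the list alone). Glycolysis genes fell in 11 of 21, with Pgam2 (-2.25) and Eno3 (-2.21) (median -0.40, adjusted p = 0.00073, adjusted p = 0.53 with an estimated correlation, 2 higher and 12 lower adjusted over the list alone). Cholesterol synthesis genes rose in 6, 15 and 16 of 17, Sc4mol (2.62) and Idi1 (1.96) among them (median 1.38, adjusted p = 1.9e-08, adjusted p = 0.53 with an estimated correlation). Sarcomere genes rose in 4 and fell in 12 of 22 at 96 h, with Myl7 (-2.85) and Ttn (-1.14) lower (median -0.19, adjusted p = 0.013, adjusted p = 0.65 with an estimated correlation). Cardiomyocyte markers fell in 6 of 10 (median -0.20, adjusted p = 0.0058, adjusted p = 0.58 with an estimated correlation, 0 higher and 7 lower adjusted over the list alone).

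Stress lists split in direction over time in culture. At 24 h 14 of 18 antioxidant genes rose, with Nqo1 (3.35 ± 0.23) and Hmox1 (1.74 ± 0.36) (median 0.77, adjusted p = 6.2e-05, adjusted p = 0.38 with an estimated correlation). At the same time 10 of 17 unfolded protein response genes rose while 4 fell (median 0.40, adjusted p = 0.030, adjusted p = 0.69 with an estimated correlation, 10 higher and 5 lower adjusted over the list alone). Heat shock genes fell in 9 of 15 cases at 96 h and 1 rose (median -0.34, adjusted p = 0.00017, adjusted p = 0.56 with an estimated correlation, 1 higher and 11 lower adjusted over the list alone). Genes of the cytokine and inflammation list fell in 15 of 22 cases at 96 h, Nfkbia (-2.94), Cxcl10 (-2.88) and Cxcl1 (-2.84) among them (median -1.07, adjusted p = 1.3e-07, adjusted p = 0.38 with an estimated correlation, 1 higher and 16 lower adjusted over the list alone). Interferon response genes went both ways at 24 h, 8 higher with Mx2 (2.71) and Usp18 (2.15) and 7 of 18 lower with Rsad2 (-3.03) and Irf1 (-1.93) (median 0.21 but mean -0.06 and test direction down, adjusted p = 0.97). All 5 erythroid genes fell by 96 h (median -3.04, adjusted p = 0.00014, adjusted p = 0.21 with an estimated correlation). Of 10 fibroblast markers 7 fell and 1 rose at 6 h (median -0.999, adjusted p = 0.0058, adjusted p = 0.65 with an estimated correlation, 1 higher and 8 lower adjusted over the list alone). At 96 h 3 fell and 2 rose (median 0.13 but mean -0.04 and test direction down, adjusted p = 0.86, 3 higher and 3 lower adjusted over the list alone).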

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

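The tests of exchanged labels, of fewer fibroblasts, of fewer macrophages at 96 h, of more macrophages at 6 h, of harvests for fibroblast and cell cycle transcripts and for longitudinal stretch (except against transverse stretch), and of splits with the 96 h grouping kept were chosen only after the results they address were seen.

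Replicate 1 of the 24 h isotropic stretched group lay at 0.92 on the axis from 24 h (0) to 96 h (1), and replicate 1 of the 96 h isotropic unstretched group lay at 0.233. A property of harvest 1 is argued against by the other isotropic arrays of that harvest, which lay near their labelled times, at 0.0698 (24 h unstretched) and 0.781 (96 h stretched). Exchanged labels of the 2 arrays stay open and are consistent with these positions and with the authors' deposited table, where all 15 fold change columns match the group means after the exchange and 13 match before it. The residual SD was smaller for 12650 genes with the arrays exchanged and for 5949 genes as labelled. The design gives no biological explanation, and none was tested.

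Macrophage, fibroblast and cell cycle transcripts were lower in stretched anisotropic tissue at 96 h, and a difference between harvests is argued against after transverse stretch by their medians within harvests 1 and 2 (macrophage -1.55 and -1.4, fibroblast -1.42 and -1.43, cell cycle -1.84 and -0.555). For longitudinal stretch a harvest difference shared by all time points is argued against by medians, in the same order, of -1.08, -1.36 and -0.993 with harvest as a term and -1.11, -1.14 and -1.22 with each harvest's own 0 h array subtracted. One that arises by 96 h cannot be told apart from longitudinal stretch, because only harvest 1 held such arrays beside others of 96 h, where the medians were -1.14, -1.02 and -1.04, and they were -0.947, -0.443 and -0.439 in a fit to the 96 h arrays alone. Fewer fibroblasts as the whole cause of the fall of fibroblast markers cannot be told apart from lower transcript levels per cell. The mean change of -0.651 of Col1a1, Col1a2 and Col3a1 lay under the bound of -0.5 set for this cause after the results were seen. Yet it lay 1.28 (SE 0.566, over genes and not arrays) above the median of -1.93 of the other 7 markers, so these collagens fell less. Fewer macrophages stay open and are consistent with 11 of 12 markers below -0.3 after transverse and 11 of 12 after longitudinal stretch, and lower transcript levels in an unchanged number of cells, not tested, stay open as well.

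After 6 h of longitudinal stretch 18 genes were higher, Csf2, Cxcl2, Il1a and Nos2 among them, by a median of 1.26. More macrophages are argued against by a median macrophage marker change of 0.0715 (SE 0.14, over the 12 markers, which are not independent, and not over arrays). A difference between harvests as the whole cause is argued against by a fit to the 6 h arrays alone with harvest as a term. There the 21 genes that passed without the term had a median of 0.965 (SE 0.163, over genes and not arrays) and 12 passed. They were chosen from these same arrays, which favours a high median. In harvest 5, the only harvest with both groups, 18 of 18 genes were higher, by a median of 1.23. These 18 had passed in a fit that included harvest 5, so their sign there was largely fixed and decides nothing. Against transversely stretched tissue of the same harvest their median difference was 0.691 in harvest 3, 0.388 in harvest 4 and 1.08 in harvest 5. A response to the direction of stretch stays among the open explanations.

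In the 0 h group the Atp2a2 signal of replicate 1 (12.68) stood apart from the group's median of 12.53, with a gap of 0.69 of the whole range to its neighbour. It was 1 of 19 values tested in this way, and chance sets an array apart in about 1 of 20 groups. The response to stretch differed between tissue layouts at 6 h in 5 genes by the F test, and 8 of 100 splits of the arrays gave as many (highest other 17), so chance is not excluded. At 24 and 96 h, with 0 genes, 100 of 100 splits gave as many, and the highest of the others, 489 and 39, point to a structure of the samples whose source was not tested. The test of change over time called 64 genes for isotropic stretch, and 19 of 100 splits gave as many, so chance is not excluded. The highest other, 980, points to a structure whose source was not tested; it set both arrays in doubt among the stretched ones. For longitudinal stretch it called 325 genes, and only the real 1 of 100 splits drawn gave as many (highest other 222). Undrawn ones gave up to 580, so chance is not excluded. For transverse stretch it called 526 genes, and 7 of 100 splits (highest other 1277), all with the real grouping of the 96 h arrays, gave as many, so chance is not excluded. With the 96 h grouping kept, 40 (isotropic), 12 (longitudinal) and 52 (transverse) of 100 splits of the 6 and 24 h arrays gave as many genes (highest others 435, 580 and 1753). In none of the 3 is chance excluded for the grouping at 6 and 24 h, so these counts do not set a change over time apart from the response at 96 h. Transverse and longitudinal stretch differed in 4 genes at 6 h, and 2 of 10 splits, too few for a share under 0.05, gave as many. The other split of these, with 4 genes, put both harvest 3 arrays together, and within each of the 3 harvests the 4 genes had the same sign. Among 8854 probe sets without a single gene symbol, which no comparison above used, 143 passed after 96 h of transverse stretch, 61 higher and 82 lower, or 1.62% against 15% of the genes.

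Comparisons of 3 arrays with 3 have 10 splits, too few for a share under 0.05. For stretch of isotropic tissue the real count and the highest other split were 1 and 1 at 6 h (2 of 10 splits as large), 731 and 111 at 24 h (1 of 10) and 546 and 374 at 96 h (1 of 10). The other split with 1 gene put both harvest 3 arrays together, and the split with 374 genes both harvest 1 arrays. For longitudinal stretch they were 18 and 0, 414 and 0, and 1804 and 2 (1 of 10 each), and for transverse stretch 0 and 0 (10 of 10), 271 and 49 (1 of 10) and 2797 and 3 (1 of 10). Between the directions the 24 and 96 h counts were 0 (10 of 10 each), against 5 in a split with both harvest 4 arrays together and 34 in a split with both harvest 1 arrays together. Between unstretched anisotropic and isotropic tissue they were 0 and 0 at 6 h (10 of 10), 0 and 65 at 24 h (10 of 10) and 3 and 7 at 96 h (3 of 10). The splits with 65 and 7 genes put both harvest 1 arrays together, which points to a structure by harvest. Time in culture had 84 splits, of which only the real 1 was as large at each time, so chance is excluded. The highest others at 6 h (2280 genes) and 24 h (3062) set the 0 h arrays of the same 3 harvests against all the rest, and that at 96 h (3663) joined replicates 2 and 3 of the 96 h group to the 0 h array of harvest 6.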

How the results depend on the processing

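Signal above background was not tested per gene, so that changes of dim genes are bounded less well than those of bright ones. Leaving out the dimmer genes kept 9301 of 18602. With 3 arrays in a group, counts of genes depend on few arrays, and a count of 0 does not show that nothing changed. Of 420 gene by comparison values that were checked 256 passed, and 166 of these passed with every single array left out. None of those that passed changed direction under any alternative. Calls were the same in 329 of 420 cases in a fit to the arrays of the time point and 0 h alone (78 ended), in 350 with each harvest's own 0 h array subtracted (60 ended), in 371 without a harvest block (38 ended), in 409 with the 2 arrays exchanged (5 ended) and in 408 with both left out (9 ended). For the moved counts below the cause was not tested, except that leaving out arrays or dim genes leaves less to test. Exchanging the 2 arrays and leaving both out were chosen after the data were seen. For the F tests over time the fit to the arrays of the time points and 0 h alone is the main fit itself and gave no value of its own.

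Without the harvest block 20 of 28 results kept their call or count. The others were 0 genes for isotropic stretch of 6 h, 335 at 24 h and 230 at 96 h, 238 for longitudinal stretch of 24 h, 2 between directions at 6 h, 1 between unstretched layouts at 96 h, and 17 (isotropic) and 339 (transverse) for change over time. Dropping the pairing by harvest moved no other count by over 1.5 times. With harvest as a random block (consensus correlation 0.18), 22 of 24 stayed, and the others were 12 genes between unstretched layouts at 96 h and 10 for response by layout at 6 h.

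With each harvest's own 0 h array subtracted 12 of 24 stayed. The counts were 0, 198 and 91 for isotropic stretch of 6, 24 and 96 h, 11 and 122 for longitudinal stretch of 6 and 24 h, and 131 and 1473 for transverse stretch of 24 and 96 h. They were 0 between unstretched layouts at 96 h, 2 for response by layout at 6 h, and 9, 104 and 141 for change over time under isotropic, longitudinal and transverse stretch. In a fit to the arrays of the time point and 0 h alone 14 of 21 stayed. The moved counts were 13 and 222 for isotropic stretch of 6 and 24 h, 63, 27 and 822 for longitudinal stretch of 6, 24 and 96 h, 6 for transverse stretch of 24 h and 0 between unstretched layouts at 96 h.

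With dim genes left out 24 of 28 stayed, and the counts moved to 3 for longitudinal stretch of 6 h, 0 between directions at 6 h, 1 between unstretched layouts at 96 h and 1 for response by layout at 6 h. Trend and robust options, repeated quantile normalisation and the second deposited value table kept 24 of 24. Of 558 list tests 182 passed with the preset correlation (59 up and 123 down) and 7 with an estimated one.

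Exchanging the 2 arrays kept 18 of 28 and gave 0, 1513 and 1483 genes for isotropic stretch of 6, 24 and 96 h, 803 for longitudinal and 647 for transverse stretch of 24 h, 4 between directions at 24 h, 1 for response by layout at 96 h, and 302, 822 and 1185 for change over time. Leaving both out kept 16 of 28 and gave 0, 1198 and 1112 for isotropic stretch, 858 and 2757 for longitudinal stretch of 24 and 96 h, 692 for transverse stretch of 24 h, 0 between unstretched layouts at 96 h, 9 and 1 for response by layout at 6 and 96 h, and 278, 852 and 1275 for change over time.

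With each array left out in turn 136 of 216 counts stayed, and an arm left with 2 arrays was assumed to vary like the other groups. Lowest to highest, isotropic stretch gave 0 to 3 genes at 6 h, 263 to 1109 at 24 h and 194 to 858 at 96 h. Longitudinal stretch gave 149 to 339 at 24 h and 1016 to 2022 at 96 h, and transverse stretch 0 to 1 at 6 h, 37 to 694 at 24 h and 1601 to 2878 at 96 h. Between directions the counts were 1 to 8, 0 to 286 and 0 to 15 at 6, 24 and 96 h, and between unstretched layouts 0 to 39 at 24 h and 0 to 242 at 96 h. Response by layout gave 3 to 12, 0 to 102 and 0 to 22, and change over time 29 to 292 (isotropic), 154 to 542 (longitudinal) and 215 to 767 (transverse). Longitudinal stretch of 6 h, unstretched layouts at 6 h and time in culture at each time stayed in every case.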
